A study of Cyanidioschyzon merolae with 48 samples.

How the data were processed

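The 48 arrays came from 16 groups of 3 biological replicates, per the series' design text. Algal mats were shaken off rocks at Lemonade Creek and Dragon Spring and flash-frozen, and total RNA was extracted with a soil RNA kit and treated to remove DNA, per the labels' protocols. Per the same protocols, cDNA was labelled with Cy3 for NimbleGen one-colour arrays, so each array holds 1 sample. At Lemonade Creek the samples of 7 dates came from under 1 of 2 filter materials, installed in triplicate. The OP-4 material let about 90% of visible light, UVA and UVB pass. The UF-5 material passed a similar share of visible light and blocked 99.9% of UV below 390 nm. The samples of January 2008 and June 2007 came from Dragon Spring without a filter. Groups were taken from the labels alone. For 3 dates the day of the month differs between a sample's title and its other labels (20 and 8 for August 2008, 16 and 6 for November 2009, 22 and 10 for April 2010), and month and year were used. The growth protocol has sampling start in July 2007 while the labels of a Dragon Spring group give June 2007, and the labels were used.

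The authors deposited for each array a table of RMA intensity on a linear scale, with a value per feature in each of 4 blocks and a row for random control probes, per the file headers. RMA is named in the submitters' processing notes, and its version, its background model and the set of arrays it was run on are not given in the sources used here. The authors also deposited a log2 table of the whole series, which differed from the log2 of the mean of the 4 blocks by at most 0.005, the rounding of its 2 decimals. All of its sample columns could be matched to a sample. Raw scanner files were not used here, so the background correction could not be varied. Background correction and normalization across arrays that differ in true signal can shrink or shift differences, most of all for dim features.

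The arrays carry 6699 features of the Cyanidioschyzon merolae genome, of which 6646 have 5 probe pairs. By their identifiers and the files' descriptions, 4935 are protein-coding genes, 711 possible transcribed regions, 519 hypothetical transcripts, 338 repetitive elements, 140 sequence reads, 53 strain regions and 3 RNA genes. Of all features, 193 are plastid-encoded and 31 mitochondrial. The files give 2884 features a usable product name. Locus tags of 5216 features matched the RefSeq table of assembly ASM9120v1, among them 4698 of the 4714 nuclear protein-coding features, and none of its coordinates were used. Mats can hold other strains and organisms than the one the probes were designed on, and the arrays cannot tell their RNA apart. A list of 38 conserved genes was kept for this reason.

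Random-probe signal was between 225.9 and 635.3 intensity units per array, with 370.3 the second highest. The median feature lay 9.8- to 32.2-fold above it, and 3.78 to 10.31% of features lay under 2 times it. In at least 1 group 620 features were under that level on all 3 arrays, and 52 were on all 48 arrays. Where a named gene was under it on every array of a compared group, its change is given as at least N-fold, with the dim group's value set to the higher of its own and 2 times the random-probe signal. The number of arrays limits the precision. The median standard error was 0.082 for the mean of 7 dates, 0.217 for 3 against 3 arrays and 0.153 for 6 against 6, all on the log2 scale.

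Computed here, the 4 blocks were averaged, log2 was taken, and limma (3.58.1, R 4.3.3) was fitted with 1 mean per group over all 48 arrays, with moderated variances (32 residual and 3.1 prior degrees of freedom). The comparisons were OP-4 minus UF-5 as a mean of 7 dates with equal weight and at each date, an F test that the 7 differences are equal, and the difference in summer (August 2008, July 2009, July 2010) minus that in winter (February 2009, January 2010). Dates were compared by an F test over the 7 Lemonade Creek date means and by 3 summer minus winter pairs that share no array. Further results were the number of features called the same way in all 3 pairs, the difference of the Dragon Spring pair from the mean of the other pairs, and a fit on 7 date means with the date as the replicate. P-values were adjusted by Benjamini-Hochberg over all features within a comparison, with a threshold of 0.05, and those of a single date each over its own family. Adjusted p-values in the text are from limma. They measure the spread between samples within groups, pooled over all 16 groups, and not the spread between years. The median SD of a group ran from 0.124 (July 2010 OP-4) to 0.321 (July 2009 UF-5). Where the compared groups spread widely, a pooled estimate can thus make p-values too small.

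Gene lists were fixed as keyword patterns on product names, and 21 lists with at least 4 members were tested by limma's camera with a preset correlation of 0.01, in 5 comparisons. The lists were photolyase and cryptochrome, DNA repair, heat shock and chaperones, antioxidant, phycobilisome and light harvesting, photosystem subunits, tetrapyrrole and chlorophyll synthesis, carotenoid and isoprenoid synthesis, Calvin cycle, ribosomal proteins, DNA replication and cell cycle, histones, proteasome and ubiquitin, nitrogen assimilation, metal and arsenic handling, respiration and ATP synthase, glycolysis and storage carbohydrate, fatty acid and lipid synthesis, conserved genes, plastid-encoded genes and mitochondrion-encoded genes. A gene can be in several lists. The patterns of the photosystem list also caught 4 genes similar to Mbb1, a maturation factor of psbB mRNA, which are not photosystem subunits, and the list was left as fixed. Of 105 list tests, camera called 21, of which 1 (carotenoid and isoprenoid synthesis in the mean UV difference) was called with an estimated correlation and 11 by fry, a test of whether a list's genes move one way on balance.

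Groups, tests, lists, the first set of other settings and the rule for named genes were fixed before the data were examined. The rule names the 10 largest differences each way among called features with a product name for the mean UV difference and each season comparison, 3 each way at single dates, up to 4 list members with the smallest adjusted p, and every measured photolyase and cryptochrome gene. Image names in the files sort 36 arrays into 5 slide groups. The other 12, all of August 2008 and Dragon Spring, have names of another form and were taken as a 6th group, though the names do not show that they shared slides. The 6 groups were used as a block, so slide-block and within-slide counts of those dates rest on this choice. Replicate numbers were taken to pair the 2 filters of a date where the deviations of all 3 same-numbered pairs correlated over 0.1, which held in July 2009 alone (r = 0.457, 0.357 and 0.462). That pairing comes from the values and not from the labels. That first set held a filter on the dimmest features (a share of 0.25), quantile normalization, median centring, the whole-series table, another variance model, array quality weights, a replicate block, a slide block, a 2-fold threshold, fits on the compared arrays alone, each array left out in turn, and other list tests. The default estimate of the array weights did not converge, so the gene-by-gene method was used. Chosen after the data were seen were leaving out 4 doubted arrays together, the random-probe signal as a covariate, the median of the 4 blocks, and fits within slide groups holding both sides of a comparison. For within-slide UV fits November 2009 drops out, since no slide group holds both of its filters.

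The fits were tested on simulated data in which 67, 67 and 66 of 6699 features were changed by 3 sizes. At a 2-fold change, 97% were recovered for the mean UV difference, 74.6% for a single date, 86.6% for July 2010 minus January 2010, 74.6% for June 2007 minus January 2008, 77.6% for the UV difference in summer minus winter, and 64.2% for the difference between sites. With dates as replicates 13.4% of 2-fold and 70.1% of 4-fold changes were recovered, and the F test over UV differences found 35.8% of 2-fold and 87.9% of 4-fold changes. In the list simulation, where noise was independent between features, none of 20 unshifted lists was called. It cannot show how often camera calls lists whose genes vary together, as plastid-encoded genes did (estimated correlation 0.574). Numbers were summarised with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.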

Results

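Transcripts of Cyanidiales mats, red algae that cover rocks in hot acidic springs, were measured on 48 one-colour arrays from 2 sites in Yellowstone. Lemonade Creek gave 42 arrays, from 7 dates between August 2008 and July 2010 and from 2 filter materials, with 3 arrays per date and filter. The OP-4 filter let UV through with visible light and the UF-5 filter blocked 99.9% of UV below 390 nm. Their difference was taken to measure UV exposure, and higher under UV means higher under OP-4. The filter also went with position on the slide in January, April and July 2010, where UF-5 arrays followed OP-4 arrays. Elsewhere positions of both filters on a slide are not known, and in November 2009 the filters shared no slide group. Among UV differences, position was tested only for the called carotenoid genes. Dragon Spring gave 3 arrays in January 2008 and 3 in June 2007, without filters. Differences are given as log2 values with their standard errors, and higher or lower refers to an adjusted p under 0.05 in limma over 6699 features. The median log2 intensity of an array was between 12.60 and 12.87. On 4 arrays something stood apart. November 2009 UF-5 replicate 3 had the highest random-probe signal, 635.3 against at most 370.3 on the others. April 2010 UF-5 replicate 3 had a mean correlation across features of 0.803 with its group, against 0.978 between the other replicates. November 2009 OP-4 replicate 3 had 0.877 against 0.953, and the image name of July 2009 UF-5 replicate 1 carries the word flawed. April 2010 UF-5 replicate 3 and November 2009 OP-4 replicate 3 were the only arrays of their slide group. November 2009 UF-5 replicate 1, not among the 4, had a mean correlation of 0.873 against 0.923.

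The first question was which transcripts differ with UV on average over the 7 dates (21 arrays under each filter). CMR353C, similar to a respiratory burst oxidase, an enzyme that makes superoxide, was higher under UV by 0.87 ± 0.08 (adjusted p = 6.02e-09) and was above 0 on all 7 dates. CMG129C, a MYB-related protein, was higher by 0.82 ± 0.11 and CMT418C, similar to aspartokinase/homoserine dehydrogenase of amino acid synthesis, by 0.62 ± 0.07 (adjusted p = 2.24e-05 and 3.2e-07). Enzymes of carotenoid synthesis rose with them, among them zeta-carotene desaturase CMT061C by 0.55 ± 0.09 and phytoene dehydrogenase CMP341C by 0.53 ± 0.08 (adjusted p = 0.000178 and 8.52e-05). Further named genes among the 10 largest increases were the SEL1-like CMB078C (0.69 ± 0.11), the RNA-binding hnRNP H3-like CMF163C (0.67 ± 0.10), the psbB mRNA maturation factor Mbb1 CMQ412C (0.55 ± 0.15), a microsomal glutathione S-transferase, CMS309C (0.53 ± 0.15), and CMO324C of folate synthesis (0.53 ± 0.15), with adjusted p between 6.81e-05 and 0.0398. Only 4 genes with a product name were lower. They were CML009C, related to the vesicle fusion protein SLY1 (−0.34 ± 0.10), lactoylglutathione lyase CMD108C (−0.25 ± 0.05) and glyoxalase I CMR395C (−0.23 ± 0.05), both detoxifying methylglyoxal, and ribosomal protein L37A CMN315C (−0.14 ± 0.04). In all, limma called 283 features, 4.2% of those measured, 227 higher and 56 lower. Of the 227, 198 were protein-coding and 113 were above 0 on all 7 dates, and of the 56, 29 were repetitive elements. Changes were small. Those of at least 2-fold were 6, named here after their values were seen, the hypothetical protein CMK034C (1.02) and transcribed region CMT033Z (1.01) higher, and the hypothetical protein CMR094C (−1.33) and repetitive elements CMT148X (−1.10), CMD166X (−1.07) and CMH228X (just past 2-fold) lower. The count was 80 (78 higher, 2 lower) with the slide as a block, 721 (376 and 345) within slides holding both filters, 122 (113 and 9) with random-probe signal as a covariate, 551 (343 and 208) without the 4 arrays that stood apart and 1414 with array weights. It was 184 without April 2010 OP-4 replicate 1, 188 without January 2010 UF-5 replicate 3, 435 without August 2008 UF-5 replicate 3, 647 without November 2009 UF-5 replicate 1 and 755 without April 2010 UF-5 replicate 3. The lower calls were the least stable part, 22, 21, 121, 286 and 316 without these 5. Without 1 of 17 other arrays they also moved by over 1.5 times. They were 24, 111, 30 and 32 without February 2009 OP-4 replicates 1 and 3 and UF-5 replicates 1 and 3, 25 and 30 without April 2010 UF-5 replicates 1 and 2, and 25 and 24 without August 2008 UF-5 replicates 1 and 2. They were 37, 32 and 35 without July 2010 OP-4 replicates 1, 2 and 3, 34 and 33 without its UF-5 replicates 2 and 3, and 31 and 88 without July 2009 OP-4 replicate 2 and UF-5 replicate 3. Without January 2010 OP-4 replicate 2 or November 2009 UF-5 replicate 3 they were 30. With the slide as a block none of the 4 named lower genes kept its call (adjusted p between 0.0691 for CMR395C and 0.386 for CML009C), nor did CMQ412C (0.167), CMS309C (0.117) and CMO324C (0.332). With the random-probe covariate CML009C (0.272), CMN315C (0.15), CMQ412C (0.164), CMS309C (0.139) and CMO324C (0.295) lost it. CML009C also lost it within slides (0.0604) and CMS309C without the 4 arrays (0.0631). CMR353C, CMG129C, CMT418C, CMT061C, CMP341C, CMB078C and CMF163C kept theirs in all 4 of these fits.

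Among the gene lists, carotenoid and isoprenoid synthesis was higher under UV as a group (camera adjusted p = 2.05e-05, median 0.14, adjusted p = 0.0464 with an estimated correlation). Of its 14 genes 5 rose, over all features and adjusted over the list alone, also including phytoene desaturase CMK151C by 0.38 ± 0.06, the desaturase precursor-like CMP289C by 0.33 ± 0.07 and deoxyxylulose-phosphate synthase CMF089C, which starts plastid isoprenoid synthesis, by 0.17. Within slides the list's camera adjusted p was 1.5e-05. Fatty acid and lipid synthesis had 4 higher genes of 24 (5 adjusted over the list alone), led by a delta 9 desaturase, CMJ201C, with 0.48 ± 0.08, and by CMM122C with 0.38 ± 0.08. In the antioxidant list 3 of 26 rose, including peroxiredoxin Q CMI113C by 0.22 (4 higher and 1 lower adjusted over the list alone). Respiration had 2 higher of 50, with CMG064C at 0.36, and the photosystem list 2 of 38, CML157C at 0.25 and CMQ412C, which are both similar to the psbB mRNA maturation factor Mbb1, so that no photosystem subunit was called, and these counts were the same adjusted over the list alone. Each of 7 further lists had 1 changed gene. These were the repair helicase RAD26 CMO092C (0.29) of 48 DNA repair genes, an arsenite-translocating ATPase, CMR284C (0.24), of 25 metal genes, CMF187C (0.35) of 78 proteasome and ubiquitin genes and cryptochrome DASH CMJ130C (0.42) of 9 photolyases and cryptochromes, which were also called adjusted over the list alone. The others were the protease subunit HslU CMT122C (0.49) of 53 heat shock genes, a ribonucleotide reductase subunit, CMK035C (0.25), of 54 cell cycle genes and L37A of 175 ribosomal proteins, for which the lists gave 0 adjusted over the list alone. No gene was called by limma in phycobilisome (15 genes), tetrapyrrole (21), Calvin cycle (16), histones (6), nitrogen (8), glycolysis (35), conserved (38), plastid-encoded (190) or mitochondrion-encoded (31) lists, over all features or adjusted over the list alone. With the slide as a block CMP289C (adjusted p = 0.0927), CMI113C (0.099), CML157C (0.0628), CMO092C (0.106), CMF187C (0.18), CMT122C (0.386) and CMK035C (0.162) lost the call. With the random-probe covariate CMI113C (0.157), CMO092C (0.0507), CMT122C (0.239) and CMK035C (0.233) did, within slides CMT122C (0.0822) and without the 4 arrays CMI113C (0.0587). Camera gave no other list than carotenoid synthesis an adjusted p under 0.438. The median, mean and test differed in sign for photosystem, Calvin cycle, ribosomal, nitrogen, glycolysis, conserved and plastid-encoded lists, none of them called.

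**Figure D1:**
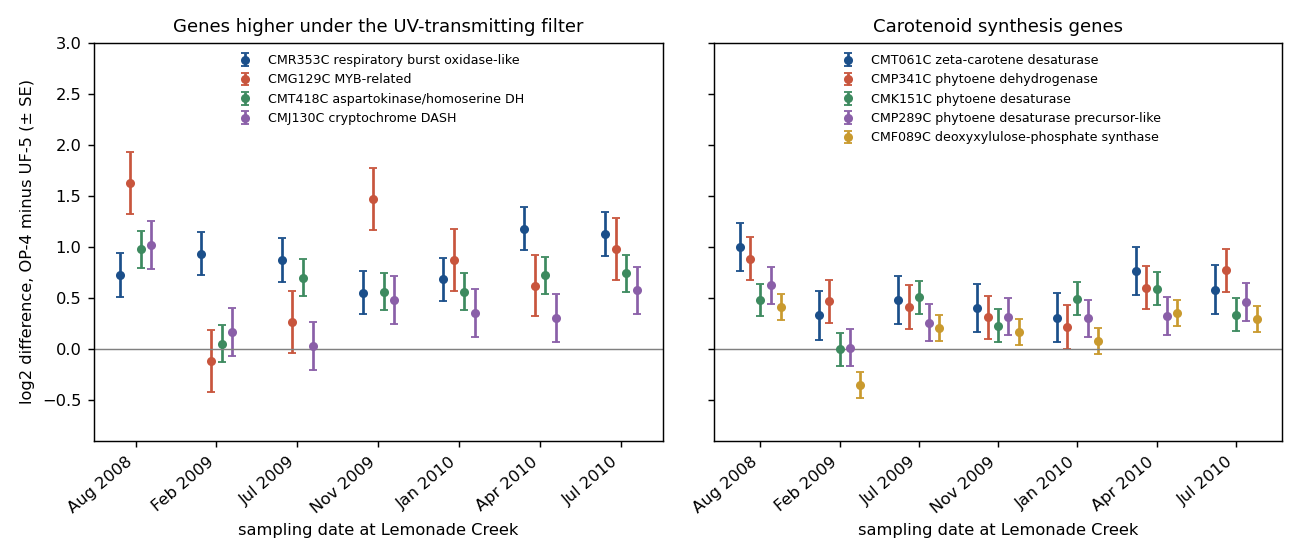
Log2 difference of OP-4 minus UF-5 (vertical axis, points with standard error bars, 3 arrays per filter) at the 7 Lemonade Creek dates (horizontal axis) for 4 genes higher under UV (left) and 5 carotenoid synthesis genes (right). CMR353C lies above 0 at every date, from 0.55 in November 2009 to 1.18 in April 2010, while CMG129C ranges from −0.12 in February 2009 to 1.63 in August 2008.

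Photolyases and cryptochromes, the light-driven DNA repair enzymes and blue-light receptors of one family, were examined one by one. In the mean over dates only cryptochrome DASH CMJ130C was called, higher under UV by 0.42 ± 0.09 (adjusted p = 0.00332). The second cryptochrome DASH, CMA044C, had 0.33 ± 0.16, 6-4 photolyase CMO348C 0.13 ± 0.13, class II photolyase CMH170C 0.11 ± 0.05, photolyase CMH274C 0.09 ± 0.08, PHR2 CMD121C 0.03 ± 0.04, the photolyase-like CMJ288C 0.02 ± 0.06, and cryptochromes CMM076C −0.25 ± 0.16 and CMQ453C −0.10 ± 0.07, with adjusted p between 0.206 and 0.894. By date, in the order August 2008, February 2009, July 2009, November 2009, January 2010, April 2010 and July 2010, CMJ130C had 1.02, 0.17, 0.04, 0.48, 0.35, 0.30 and 0.58, and was called in August 2008 (adjusted p = 0.0478). That call was lost with the median of the 4 blocks (adjusted p = 0.0803) and with the replicate number as a block (0.108). In the same order CMA044C had 0.99, −0.56, −0.42, 1.20, 0.12, 0.18 and 0.83, and CMO348C had 0.30, −0.21, −0.32, 0.36, 0.26, −0.01 and 0.52. CMH170C had 0.28, 0.04, −0.00, −0.09, 0.20, 0.23 and 0.08, and CMH274C had 0.38, −0.11, −0.12, 0.26, 0.06, 0.04 and 0.11. CMJ288C had −0.06, 0.21, −0.14, 0.04, 0.24, −0.04 and −0.09, and CMD121C had 0.03, −0.05, 0.12, 0.11, 0.04, −0.03 and −0.03. CMM076C had 0.41, −0.85, −1.05, −0.26, −0.21, −0.22 and 0.46, and CMQ453C had −0.28, −0.11, −0.23, 0.06, −0.09, −0.15 and 0.09. None of these other values passed the test. The UV difference in summer minus that in winter was 0.29 for CMJ130C, 0.69 for CMA044C, 0.14 for CMO348C, −0.00 for CMH170C, 0.15 for CMH274C, −0.32 for CMJ288C, 0.05 for CMD121C, 0.47 for CMM076C and −0.04 for CMQ453C, none of them called.

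At single dates (3 arrays per filter) most features were called in February and November 2009. In February 2009, 460 features were higher and 208 lower under UV, with the photosystem II plastid genes CMV127C (2.41 ± 0.76) and CMV141C (2.39 ± 0.65) and the octaprenyltransferase CMV116C (1.98 ± 0.62) highest. All 3 lay under 2 times the random-probe signal on 2 of the 3 UF-5 arrays. They lost the call with the slide as a block (adjusted p between 0.0621 and 0.107) and within slides (between 0.0551 and 0.141). With the random-probe covariate CMV127C (0.0863) and CMV116C (0.0838) lost it too. The polyadenylation factor FIP1-like CMR160C (−2.05 ± 0.54), a nucleolar phosphoprotein, CMS127C (−1.95 ± 0.54), and tyrosine-tRNA ligase CMI042C (−1.89 ± 0.44) were lowest. In November 2009, 239 were higher and 120 lower (211 lower without OP-4 replicate 3, 188 and 169 after median centring, and the other way round, 95 and 208, without the 4 arrays that stood apart), led by ribosomal protein L34 CMP012C (3.03 ± 0.71), translation factor eIF-5 CMH058C (1.93 ± 0.44) and the hemolysin-like CMM140C (1.78 ± 0.44). Plastid cytochrome b6-f subunit V CMV139C (−3.50 ± 0.71), plastid ribosomal protein S18 CMV213C (−3.09 ± 0.68) and mitochondrial cytochrome c oxidase subunit I CMW019C (−3.05 ± 0.76) fell most. Adjusted p-values of these 12 genes were between 0.00928 and 0.0404. November 2009 held the array with a random-probe signal of 635.3, its filters shared no slide group, and limma called 0 features with the slide as a block against 359 without it (100 and 1649 at an unadjusted p under 0.05). With that block CMM140C, CMV213C and CMW019C had −0.18, 0.41 and 0.92. The count in November was 68 with the random-probe covariate, 0 with only its own 6 arrays, 0 without OP-4 replicate 1 or UF-5 replicate 2, 6 without UF-5 replicate 3 and 1088 without UF-5 replicate 1. February had 374 with the slide as a block, 296 within its slide group and 1419 without the 4 arrays that stood apart, and 9 without OP-4 replicate 1, 322 without UF-5 replicate 1, 370 without UF-5 replicate 2 and 2 without UF-5 replicate 3. Of the calls of both months 5 had the same direction, against 16.4 higher and 3.7 lower for independent lists, and 33 had opposite directions.

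The other 5 dates had fewer calls, an order of dates that array weights changed. With them August 2008 had 813, July 2009 168, January 2010 1883, April 2010 127 and July 2010 1404, against 1504 in February and 1245 in November 2009. In August 2008, 13 features were higher and 2 lower, with CMG129C (1.63 ± 0.30), cryptochrome DASH CMJ130C (1.02 ± 0.24) and CMT418C (0.98 ± 0.18) the largest increases of named genes. In July 2009, 14 were higher and 4 lower, among them MoeB of molybdenum cofactor synthesis, CMM289C (−0.76 ± 0.17), and the Raf-like kinase CMG108C (−0.51 ± 0.10). With the replicate number as a block 161 were called (107 higher, 54 lower). That pairing was read from these same values, and the block takes out the variation they share, so the rise lends the calls no support. In April 2010 CMR353C was the 1 feature called, at 1.18 ± 0.21 (adjusted p = 0.0185). In July 2010 CMR353C was higher by 1.13 ± 0.21, as were CMK034C by 1.62 ± 0.32 and hypothetical transcript CMP305T by 1.14 ± 0.23, the last 2 named after their values were seen. With only the 6 arrays of the date CMR353C was not called in April (adjusted p = 0.919) or July 2010 (0.0701). Such fits called 0 features by limma in August 2008 and in July 2009 (1010 and 777 at an unadjusted p under 0.05). CMG129C and CMT418C then had an adjusted p of 0.222, CMJ130C of 0.243, and CMM289C and CMG108C of 0.401. In January 2010 limma called 0 features, with 505 at an unadjusted p under 0.05. The slide block gave 26 in August 2008, 94 in July 2009, 151 in January 2010 (6 higher, 145 lower), 2 in April 2010 and 3 in July 2010, and fits within slides gave 63, 13, 258, 2 and 2. Without the 4 arrays that stood apart, none of them from August 2008, January 2010 or July 2010, these counts were 53, 39, 178 (12 higher, 166 lower), 6 and 3. Without single arrays August 2008 had 35 (OP-4 replicate 1), 0 (OP-4 replicate 2 or 3), 1 (UF-5 replicate 1) and 6 (UF-5 replicate 2), with 21 higher and 1 lower without UF-5 replicate 3, and July 2009 had 2 (OP-4 replicate 2), 8 (OP-4 replicate 3), 1 (UF-5 replicate 1), 90 (UF-5 replicate 2) and 278 (UF-5 replicate 3). January 2010 had 1 without OP-4 replicate 1 or UF-5 replicate 1 or 2, April 2010 had 0 without any OP-4 array or UF-5 replicate 2, 2 without UF-5 replicate 3 and 1 lower and 0 higher without UF-5 replicate 1, and July 2010 had 0 without any 1 of its 6 arrays.

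**Figure D2:**
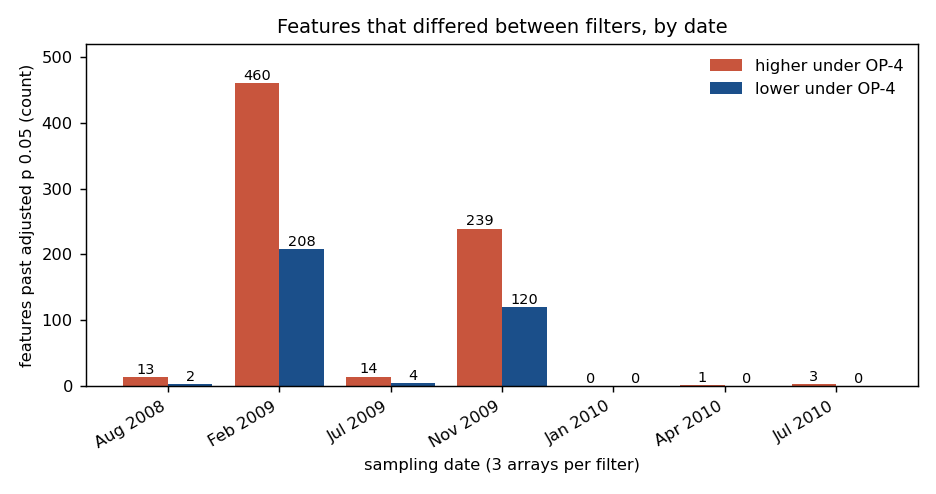
Number of features past an adjusted p of 0.05 (vertical axis) higher (orange) or lower (blue) under OP-4 at each of the 7 dates (horizontal axis, 3 arrays per filter). February 2009 has 460 and 208 and November 2009 has 239 and 120, while no other date exceeds 14 either way.

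Whether the UV difference itself changed between dates was tested by an F test over the 7 dates. It called 249 features, 160 of them protein-coding and 9 plastid-encoded. The 4 examples that follow were chosen after their values were seen. Tyrosine-tRNA ligase CMI042C ran from −1.89 in February 2009 to 1.64 in November 2009 (adjusted p = 0.0197) and fructose-bisphosphate aldolase CME145C from −0.82 to 0.74 (adjusted p = 0.0196). The SKP1 subunit CMP118C of a ubiquitin ligase ran from −0.72 in April 2010 to 1.43 in November 2009, and plastid CMV139C from −3.50 in November 2009 to 2.13 in July 2009. CMR353C was not called (adjusted p = 0.523). The F test called 17 features with the slide as a block, 79 within slides, 400 with the random-probe covariate, 621 without the 4 arrays that stood apart and 3742 with array weights. It called 1, 78 and 102 without February 2009 UF-5 replicate 3, OP-4 replicate 1 and UF-5 replicate 2, and 63, 118 and 527 without November 2009 UF-5 replicate 2, OP-4 replicate 1 and UF-5 replicate 1. Without July 2009 OP-4 replicate 2, UF-5 replicate 2 and UF-5 replicate 3 it called 140, 423 and 452, and without April 2010 OP-4 replicate 3 and UF-5 replicate 1 it called 147 and 463. Without August 2008 OP-4 replicate 2 and UF-5 replicate 2 it called 150 and 162, without January 2010 OP-4 replicate 2 and UF-5 replicate 3 156 and 161, and without July 2010 OP-4 replicate 1, OP-4 replicate 3 and UF-5 replicate 2 162, 160 and 158.

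The UV difference in summer minus that in winter was called for 0 features by limma (878 at an unadjusted p under 0.05). As lists, plastid-encoded and mitochondrion-encoded genes were lower (medians −0.31 and −0.70, camera adjusted p = 0.000413 for each) and heat shock genes higher (0.0407), none with a member called over all features. For all 3 the adjusted p = 0.862 with an estimated correlation. Adjusted over the list alone, 1 gene was higher in each of the heat shock, photosystem and carotenoid lists and 1 lower in the proteasome list, and 0 in the others. The other lists had a camera adjusted p of 0.0978 or more, and median, mean and test differed in sign for DNA repair, antioxidant, photosystem, nitrogen, metal, fatty acid and conserved lists. The feature count was 2 with the slide as a block, 31 within slides, 693 with array weights and 18 without the 4 arrays that stood apart, 1 without February 2009 OP-4 replicate 3 and 3 without July 2009 UF-5 replicate 3.

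Over the 7 Lemonade Creek dates 6058 features, 90.4% of those measured, differed between dates. The pair July 2010 and January 2010 (6 arrays each, filters averaged, all in 1 slide group) showed lower transcripts of DNA replication and mitosis in July. July arrays held positions 1 to 6 and January arrays positions 7 to 12, so date went with position on the slide. Position was tested only for the cell cycle genes called lower. MCM4 CMP356C, a subunit of the replicative helicase, fell by 2.92 ± 0.16 (adjusted p = 7.41e-16), and MCM6 CMJ261C fell by 2.29 ± 0.28. The spindle checkpoint protein MAD2 CMS347C fell by 2.59 ± 0.19, mitotic cyclin CMI203C fell by 2.28 ± 0.18 and beta-tubulin CMN263C fell by 2.01 ± 0.28. Origin recognition subunit ORC4 CMT300C was at least 3.68-fold lower and the trefoil-like CMR001C at least 3.03-fold lower, both under 2 times the random-probe signal on all 6 July arrays. Further trefoil-like genes CMA142C (−2.21 ± 0.40) and CMD191C (−1.92 ± 0.29) and retroelement CMG208C (−2.10 ± 0.53) were lower too. Higher in July were the SUMO-activating enzyme CME143C (1.97 ± 0.22), the ubiquitin-conjugating E2 variant CMF187C (1.83 ± 0.14), carbonic anhydrase CMT416C (1.79 ± 0.35), alpha-glucosidase CMA106C (1.76 ± 0.17) and CMB078C (1.60 ± 0.21). Others of the 10 largest were the ABC transporter CMN105C (1.58 ± 0.16), the HesB-like CMF122C (1.52 ± 0.34), the peroxisomal receptor-like CMK124C (1.50 ± 0.25), the TerC-like CMM279C (1.46 ± 0.14) and glutathione S-transferase CMS309C (1.44 ± 0.28). In all 1216 features were higher and 875 lower (953 and 1088 after median centring). At least 2-fold were 104 higher and 327 lower, and repetitive elements made 172 of the lower calls. With the slide as a block 2467 were called, and with array weights 4490.

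By list in 2010, DNA replication and cell cycle genes fell as a group in July, with 26 of 54 lower and 4 higher (26 and 6 adjusted over the list alone, camera adjusted p = 7.24e-08). That list had an adjusted p = 0.201 with an estimated correlation. The division protein FtsZ CMS361C, at −1.38 ± 0.15, was among them. Ribosomal proteins had 44 of 175 lower and 11 higher over all features and adjusted over the list alone (camera adjusted p = 0.000156, adjusted p = 0.603 with an estimated correlation), with L17 CMQ463C at −0.90 ± 0.12 and S18 CMB004C at −0.67. Heat shock and chaperone genes rose, 23 of 53 higher and 0 lower (25 adjusted over the list alone, camera adjusted p = 0.000209, adjusted p = 0.201 with an estimated correlation). Among them were Hsp110 CMS343C (1.19 ± 0.28), HslU CMT122C (1.10 ± 0.26) and the co-chaperone dnaJ CMF076C (0.78 ± 0.14). Photolyase and cryptochrome genes rose, 6 of 9 (7 adjusted over the list alone, camera adjusted p = 0.0136, adjusted p = 0.347 with an estimated correlation). Carotenoid synthesis rose, 6 of 14 over all features and adjusted over the list alone (camera adjusted p = 0.0407, adjusted p = 0.372 with an estimated correlation), with zeta-carotene desaturase CMT061C at 1.01 ± 0.17, phytoene desaturase CMK151C at 0.85 ± 0.11 and phytoene synthase CMQ116C at 0.56 ± 0.10. The other 16 lists were not called by camera (adjusted p 0.09 or more). In them the higher and lower genes numbered 9 and 4 for DNA repair (6 and 4 adjusted over the list alone), 11 and 5 for proteasome and ubiquitin (9 and 2), 5 and 2 for the photosystem list (5 and 1, with 3 of the 5 higher ones similar to Mbb1), 6 and 4 for respiration (5 and 4), 4 and 10 for conserved genes (4 and 11), 5 and 0 for glycolysis (4 and 0), 4 and 0 for mitochondrion-encoded (1 and 0), 2 and 3 for plastid-encoded (1 and 0) and 0 and 1 for histones (0 and 0). With the same counts adjusted over the list alone, they were 5 and 0 for Calvin cycle, 3 and 2 for tetrapyrrole, 0 and 2 for phycobilisome, 2 and 0 for nitrogen, 3 and 4 for metal, 2 and 2 for fatty acid and 2 and 5 for antioxidant lists. Nitrate reductase CMG019C was higher by 0.98. Median, mean and test differed in sign for respiration, glycolysis and fatty acid lists.

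**Figure D3:**
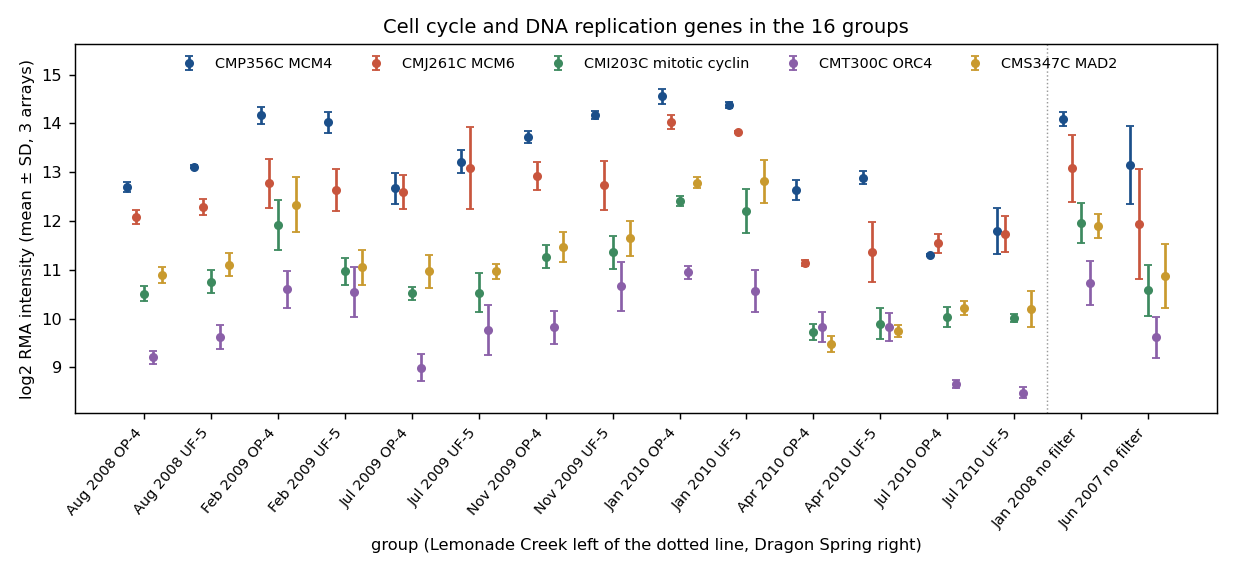
Log2 RMA intensity (vertical axis, mean with SD of 3 arrays) of MCM4, MCM6, a mitotic cyclin, ORC4 and MAD2 in the 16 groups (horizontal axis, Lemonade Creek dates and filters, then Dragon Spring). July 2010 lies below January 2010 for all 5 genes, with the largest drawn difference for MCM4 (−2.92). ORC4 lies near the random-probe signal in July 2010, so its fall can be larger than drawn.

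Between July 2009 and February 2009 (6 arrays each, filters averaged) plastid-encoded transcripts were lower in July. Plastid ribosomal protein L11 CMV102C fell by 3.02 ± 0.51 (adjusted p = 3.23e-05), L29 CMV172C fell by 2.79 ± 0.40, tryptophan synthase CMV006C fell by 2.79 ± 0.52 and the phycobilisome rod-core linker CMV051C fell by 2.64 ± 0.45. The other largest decreases were CMI109C (−2.51), S19 CMV168C (−2.47), L16 CMV171C (−2.45), L14 CMV174C (−2.38), L23 CMV166C (−2.30) and CMV139C (−2.28). Glucosamine-phosphate N-acetyltransferase CMN031C rose by 3.28 ± 0.33 (adjusted p = 4.73e-09) and SUMO-activating enzyme CME143C by 1.70 ± 0.22. The peroxisomal PMP22-like CMO253C was at least 2.83-fold higher, the HesB-like CMF122C at least 2.52-fold and the cargo receptor Erv14 CME060C at least 2.13-fold, each under 2 times the random-probe signal in 1 of the 2 February groups. The splicing protein Sm F CMQ171C (1.71 ± 0.33), CMR155C (1.62 ± 0.30), CMG092C (1.57 ± 0.27), CMS459C (1.50 ± 0.28) and aminoacylase CMA011C (1.44 ± 0.30) completed the 10 largest increases. In all 1671 features were higher and 1184 lower (1393 and 1381 after median centring), 186 and 467 of them at least 2-fold, and 230 of the lower ones were repetitive elements. The slide block gave 3166 and the slide group that held 5 arrays of each date gave 3247 (1887 and 1360).

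By list in 2009, 149 of 190 plastid-encoded genes were lower in July and 1 higher (160 and 1 adjusted over the list alone, median −1.22, camera adjusted p = 5.65e-29). That list had an adjusted p = 0.386 with an estimated correlation, and within a group the median plastid level of the arrays had an SD of 0.042 to 0.839. The change went with the 4 July arrays whose image names hold the number 700, over which the difference of plastid medians was −1.654, against −0.573 (upper bound 0.252) over the other 2. Those 4 were all 3 UF-5 arrays and 1 OP-4 array and the other 2 were both OP-4, so this contrast is largely one between the filters of July 2009. The ribosomal and light harvesting lists hold plastid-encoded genes measured on the same arrays. Ribosomal proteins, many of them plastid-encoded, had 83 lower and 12 higher of 175 (84 and 15 adjusted over the list alone, camera adjusted p = 8.17e-09, adjusted p = 0.386 with an estimated correlation). Light harvesting fell, 10 of 15 phycobilisome genes (11 adjusted over the list alone, camera adjusted p = 4.85e-06, adjusted p = 0.386 with an estimated correlation), with allophycocyanin CMV158C at −2.21 ± 0.30. The photosystem list had 13 lower and 1 higher, the Mbb1-like CMT510C, of 38, over all features and adjusted over the list alone (camera adjusted p = 0.000428, adjusted p = 0.466 with an estimated correlation), with CMV059C of photosystem I at −2.12. Tetrapyrrole synthesis had 9 lower and 4 higher of 21 (10 and 4 adjusted over the list alone, camera adjusted p = 0.0266, adjusted p = 0.386 with an estimated correlation). Antioxidant genes had 8 lower and 1 higher of 26, with manganese superoxide dismutase CMT028C at −0.71 (camera adjusted p = 0.00889, adjusted p = 0.459 with an estimated correlation). Mitochondrion-encoded genes had 5 lower of 31 (camera adjusted p = 0.0234, adjusted p = 0.763 with an estimated correlation). The other 14 lists were not called by camera (adjusted p 0.0603 or more). Cell cycle genes had 14 higher and 13 lower (15 and 13 adjusted over the list alone) and photolyases 5 higher and 0 lower (7 and 0). DNA repair had 9 and 3 (7 and 3), including UV-damaged DNA binding protein CMR264C at 1.34 ± 0.28, heat shock 13 and 5 (12 and 4), carotenoid synthesis 6 and 3 (7 and 3), respiration 5 and 14 (5 and 13) and proteasome 15 and 6 (14 and 6). Rubisco subunits CMV013C and CMV014C were lower, at −1.05 and −1.02, in a Calvin cycle list with 2 higher and 5 lower. Nitrogen had 1 and 4, metal 5 and 3 with mercuric reductase CMJ014C at 0.62 and ferritin CMP227C at −0.70, glycolysis 6 and 9, fatty acid 3 and 8, histones 3 and 1 and conserved genes 9 and 10, with actin CMM237C at −0.96. For these 7 lists and for antioxidant and mitochondrion-encoded genes the counts were the same adjusted over the list alone. Median, mean and test differed in sign for cell cycle, glycolysis and conserved lists.

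**Figure D4:**
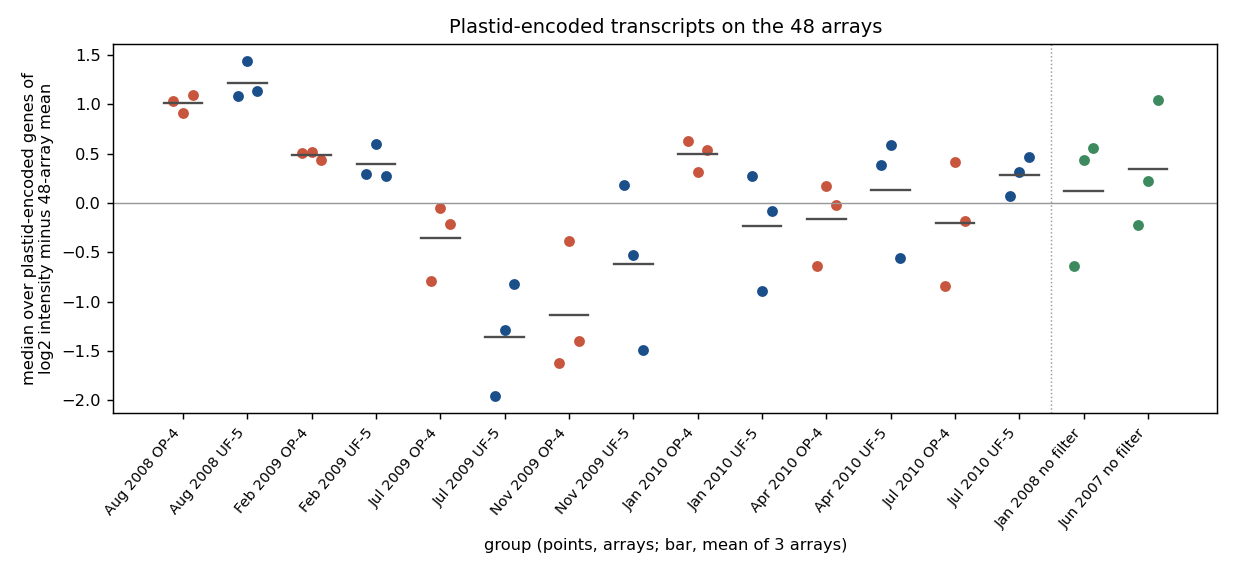
Median over the plastid-encoded genes of log2 intensity minus the 48-array mean (vertical axis) for each array (points) and the mean of 3 arrays (bars) in the 16 groups (horizontal axis). Replicates of one group spread widely, with a largest SD of 0.839, and July 2009 lies below February 2009.

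At Dragon Spring, June 2007 against January 2008 (3 arrays each) gave lower transcripts of a nitrate transporter and of cell division genes in June. Nitrate transporter CMG018C fell by 2.17 ± 0.27 (adjusted p = 2.05e-06), beta-tubulin CMN263C fell by 1.49 ± 0.39, the ribonucleotide reductase subunit CML050C fell by 1.47 ± 0.26, the mitotic kinase CDKB CMH128C fell by 1.38 ± 0.30, mitotic cyclin CMI203C fell by 1.38 ± 0.25 and polo kinase CME146C fell by 1.17 ± 0.26. Glutamate dehydrogenase CML049C (−1.14), CMT204C (−1.20), inositol dehydrogenase CMO306C (−1.16) and CMT305C (−1.13) were lower as well. Only 9 named genes were higher, the ribosome biogenesis protein Utp11 CMT211C (1.22 ± 0.31), exosome subunit Rrp4 CMT376C (1.11 ± 0.23), complex I subunit CMT198C (0.87 ± 0.17), CME111C (0.82 ± 0.16), CML146C (0.67), CMH138C (0.64), the AAA ATPase VCP CMS124C (0.59), an elongation factor, CME120C (0.56), and CMT439C (0.48). In all 34 features were higher and 49 lower. Cell cycle genes were lower as a list, 5 of 54 (10 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.000427, adjusted p = 0.714 with an estimated correlation). Camera called 4 lists higher with no member called, mitochondrion-encoded (adjusted p = 4.27e-06, median 0.88), plastid-encoded and heat shock (0.00729 each) and antioxidant (0.0163, 1 gene adjusted over the list alone). With an estimated correlation their adjusted p-values were 0.74, 0.79, 0.714 and 0.74. Of 25 metal genes 3 were lower, the iron permeases CMJ315C (−1.06) and CMQ004C (−0.93) and the zinc transporter CMS155C (−1.09), and of 6 histones the H3 variant CME099C (−1.11). Nitrogen and fatty acid lists had 1 lower gene each (2 adjusted over the list alone), glycolysis 2, respiration 1 higher and conserved genes 1 each way (2 higher and 3 lower adjusted over the list alone), and the other counts were the same adjusted over the list alone. Neither these lists nor any further one was called by camera (adjusted p 0.0709 or more), and median, mean and test differed in sign for histones, nitrogen and conserved genes. The count was 131 with the slide as a block, 0 by limma with only these 6 arrays (475 at an unadjusted p under 0.05, against 763 in the fit over 48 arrays), 141 with array weights and 159 without the 4 arrays of other dates that stood apart. It was 14 without June 2007 replicate 3, 24 without January 2008 replicate 1, 37 without January 2008 replicate 3 and 183 without January 2008 replicate 2, and without June 2007 replicate 1 the higher calls were 58. With array weights CMN263C (adjusted p = 0.357), CMH128C (0.117), CML050C (0.068), CMO306C (0.103) and CML049C (0.0736) lost the call. So did CMT211C (0.0843), CMS124C (0.0638), CME120C (0.051) and CMS155C (0.0872), while CMG018C, CMI203C and CME146C kept it.

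Of the 9 photolyase and cryptochrome genes 6 were higher in July 2010 and 5 in July 2009 at Lemonade Creek. As a list they were called in 2010 (camera adjusted p = 0.0136, adjusted p = 0.347 with an estimated correlation) and not in 2009 (camera adjusted p = 0.0603). In 2010, 6-4 photolyase CMO348C rose by 1.17 ± 0.24, the cryptochromes DASH CMA044C by 0.99 ± 0.29 and CMJ130C by 0.77 ± 0.17, CMH274C by 0.49 ± 0.15, CMJ288C by 0.32 ± 0.12 and class II photolyase CMH170C by 0.30 ± 0.09 (adjusted p between 0.000351 and 0.0394). CMQ453C (0.32), CMM076C (0.42) and CMD121C (0.07) did not pass. After median centring CMH170C (adjusted p = 0.0547) and CMJ288C (0.108) lost the 2010 call, as CMJ288C did after quantile normalization (0.0757). In 2009, CMJ130C rose by 0.85 ± 0.17, CMA044C by 0.84 ± 0.29, CMH274C by 0.82 ± 0.15, CMO348C by 0.76 ± 0.24 and CMJ288C by 0.36 ± 0.12 (adjusted p between 0.000116 and 0.0212). CMH170C (0.21), CMM076C (0.68), CMQ453C (−0.14) and CMD121C (−0.00) did not. At Dragon Spring CMH170C had −0.22, CMA044C −0.43, CMM076C −0.44, CMH274C −0.18, CMO348C −0.27, CMD121C 0.07, CMJ288C −0.09, CMJ130C −0.12 and CMQ453C 0.06, none of them called. The Dragon Spring difference minus the mean Lemonade Creek one was −0.93 ± 0.26 for CMJ130C, −1.34 ± 0.46 for CMA044C, −1.24 ± 0.38 for CMO348C, −0.83 ± 0.24 for CMH274C and −0.47 ± 0.14 for CMH170C, all 5 called (adjusted p between 0.0184 and 0.0493). It was −0.43 for CMJ288C, −0.98 for CMM076C, 0.04 for CMD121C and −0.03 for CMQ453C, which were not. With dates as replicates the summer minus winter values were 0.67 for CMJ130C, 0.69 for CMA044C, 0.74 for CMO348C, 0.38 for CMH274C, 0.06 for CMH170C, 0.17 for CMJ288C, 0.02 for CMD121C, 0.19 for CMM076C and 0.01 for CMQ453C, none called (adjusted p 0.874 or more).

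**Figure D5:**
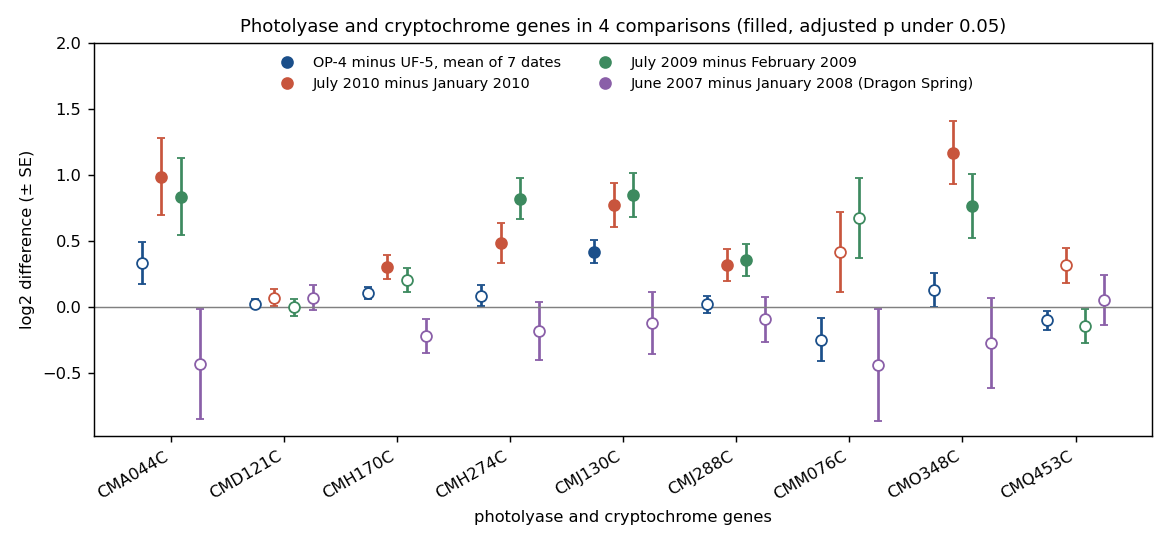
Log2 difference with standard error (vertical axis) of the 9 photolyase and cryptochrome genes (horizontal axis) in 4 comparisons, filled where the adjusted p is under 0.05. In July 2010 minus January 2010 6 of the 9 are filled and in June 2007 minus January 2008 none is.

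The next question was which features changed the same way in all 3 summer minus winter pairs. There were 14, 3 higher and 11 lower, against 3.38 and 3.64 where the Dragon Spring calls fall independently of the features that the Lemonade Creek pairs share. The 3 higher are thus no more than such a draw gives. In the order Dragon Spring, 2009 and 2010, mitotic cyclin CMI203C had −1.38, −0.92 and −2.28, MCM4 CMP356C −0.95, −1.15 and −2.92, MAD2 CMS347C −1.04, −0.73 and −2.59 and ORC4 CMT300C −1.11, −1.19 and at least 3.68-fold lower in 2010. The fatty acid elongase CML178C (−0.63, −0.44 and −0.37), CMO306C (−1.16, −0.53 and −0.84) and the sulfotransferase-like CMT454C (−1.06, −0.81 and −1.33) were also lower, and transcribed region CMA084Z (1.18, 1.05 and 1.02) was among the 3 higher ones. With array weights CMP356C (adjusted p = 0.247), CML178C (0.134) and CMO306C (0.103) lost the Dragon Spring call. The Lemonade Creek pairs shared 665 higher and 497 lower calls (303.3 and 154.6 for independent lists), with 43 opposite and a Pearson r of 0.69 across features, which are not independent replicates. The Dragon Spring differences had an r of −0.062 with 2009 and 0.062 with 2010. The count of 14 became 25 with the slide as a block, 27 without the 4 arrays that stood apart, 8 without the dimmest features and 9 after quantile normalization. It was 2 and 4 without January 2008 replicates 1 and 3, and 0 without June 2007 replicate 3, and the higher ones were 6 without January 2008 replicate 2 and 7 without June 2007 replicate 1. With the date as the replicate, 3 summer against 2 winter dates, limma called 0 features, with 304 at an unadjusted p under 0.05 and a smallest adjusted p of 0.678. It called 172 without August 2008 and 5 without January 2010.

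The seasonal difference at Dragon Spring differed from the mean of the Lemonade Creek pairs for 891 features, 413 higher and 478 lower (507 and 390 after median centring). The genes that follow were chosen after their values were seen. Nitrate transporter CMG018C was at −1.93 ± 0.30 (adjusted p = 0.000153) and nitrate reductase CMG019C at −1.61 ± 0.42 (adjusted p = 0.0118), and no gene list was tested in this comparison. Protein CMG092C (−2.21 ± 0.42), CMN031C (−2.07 ± 0.52) and UV-damaged DNA binding protein CMR264C (−1.60 ± 0.45) were lower too. Plastid L11 CMV102C (2.71 ± 0.80), allophycocyanin CMV158C (2.02 ± 0.47), ammonium transporter CMK126C (1.96) and protochlorophyllide reductase CMD190C (1.94 ± 0.60), which makes chlorophyll's precursor, were higher. Site, year and filter cannot be told apart in this comparison. The count was 1430 without the 4 arrays that stood apart, 2058 with array weights, 498 without June 2007 replicate 2, 258 without June 2007 replicate 3 and 237 without January 2008 replicate 1.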

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

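Of the tests in this part, the comparison with other seasons was chosen after the results were seen for the plastid-encoded and the cell cycle genes, as were the fits with a random-probe covariate and within slides, and the relabellings used for the F test of UV differences, the site difference and the features shared by 3 pairs.

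Among the 6 arrays of November 2009, the gap between the highest random-probe signal and the next was 0.763 of the range, which set UF-5 replicate 3 apart. It was the 1 such case in 28 sets of 6 arrays, and chance alone sets apart about 1 in 20. The UV difference itself differed between the 7 dates for 249 features by the F test. With the mean UV difference taken out first, 1 of 100 relabellings of the filters within dates, the real one, gave as many, with 11 the highest other. That argues against a chance split, provided that the arrays of a date are exchangeable. In November 2009 the filters shared no slide group. The count was 17 with the slide as a block and 1 without February 2009 UF-5 replicate 3, so it rests on few arrays. The seasonal difference at Dragon Spring differed from that at Lemonade Creek for 891 features. With an equal seasonal change at both sites taken out first, 3 of 100 relabellings of the dates, the real one included, gave as many, and the highest other gave 1002. That share is under 0.05, but 100 relabellings are too few to place it firmly there, so chance is not excluded. The count rests on 6 Dragon Spring arrays, where another split called more features than the real one, it was 237 without January 2008 replicate 1, and site, year and filter remain confounded.

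Carotenoid and isoprenoid synthesis genes were higher under UV. Background signal and slides as the whole cause are argued against by camera adjusted p-values of 2.23e-06 with the random-probe signal as a covariate (4 of 5 called genes still called) and 1.5e-05 within slides at 6 dates (5 of 5). Across these and the main setting the list's median was between 0.093 and 0.165. At the 3 dates with known positions (January, April and July 2010) the slope with position within groups made a share of −0.2 (standard error 0.26) of the difference of 0.434. That argues against a steady trend along the slide there, while a step between the positions of the filters would not be seen. For the other 4 dates position cannot be told apart from the filter, since no slide has known positions for both. The list's median was above 0 on 7 of 7 dates, from 0.041 in February 2009 to 0.305 in August 2008, as UV exposure would give. The list was picked for its mean over these same dates, and position could give the same signs, so this count lends UV no separate support. With position open at 4 dates the cause is left open.

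Plastid-encoded genes were lower in July 2009 than in February 2009. With the random-probe covariate 149 of 149 lower calls were left and within the slide group of both dates 148, which argues against background and slides as the whole cause. Of the July arrays, 4 had image names with the number 700, and over the 2 July arrays with other numbers the difference was −0.573 with an upper bound of 0.252, against −1.294 over all arrays and −1.654 over those 4. The 4 were all 3 UF-5 arrays and 1 OP-4 array and the 2 both OP-4, so the number largely went with the filter within July (plastid OP-4 minus UF-5 0.966). Within OP-4 the array with the number had a plastid median of −0.788 from the mean, against −0.052 and −0.218 on the others. With 1 such array, what that number stands for could not be parted from the filter. The number was also on April 2010 UF-5 replicate 3 and November 2009 OP-4 replicate 3, with plastid medians of −0.563 and −1.395 from the mean, against 0.385 and 0.583, and −1.624 and −0.383, on the other arrays of their groups. Season was not decided either, since the plastid median was −0.113 in July 2010 minus January 2010 and 0.276 at Dragon Spring, beside an SD of up to 0.839 between replicates of a group.

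DNA replication and cell cycle genes were lower in July 2010 than in January 2010. With the random-probe covariate 26 of 26 lower calls were left, which argues against background as the whole cause. All 12 arrays were in 1 slide group, July at positions 1 to 6 and January at 7 to 12. The slope of these genes with position within groups made a share of −0.16 (standard error 0.16) of the difference of −1.147. That argues against a steady trend along the slide, while a step between these positions cannot be told apart from the date. Season cannot be told apart from other differences between the dates. The median of the 26 genes was 0.007 in 2009, where 9 were lower and 4 higher, and −0.512 at Dragon Spring, where 5 were lower.

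Repetitive elements were lower under OP-4 (29 lower, 0 higher of 338, median −0.487), and with the random-probe covariate 2 of the 29 calls were left, the median of the 29 going from −0.772 to −0.444, with all 29 still below 0. That is consistent with a part of their difference following the random-probe signal.

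Other splits of the arrays give a measure of chance. For the mean UV difference 1 of 100 relabellings, the real one, gave 283 features or more (2 the highest other), so chance can be excluded. The same holds for the date F test (6058, 21 the highest other) and July 2010 minus January 2010 (2091, 718), each with 1 of 100. For the 14 features shared by 3 pairs only the 6 Dragon Spring arrays were relabelled and the Lemonade Creek pairs kept. The 20 labellings are too few for a share under 0.05, and 3 of them, the real one included, gave 14 or more, with 61 the highest other. July 2009 minus February 2009 also had 1 of 100 (2855), but the highest other split gave 2695. That split exchanged February 2009 OP-4 replicate 1, which lay in another slide group, with July 2009 OP-4 replicate 3, and within the shared slide group 3247 features were called. Single dates have only 10 splits, too few for a share under 0.05. The real counts and the highest others were 15 and 0 in August 2008 (1 of 10 splits as large), 668 and 0 in February 2009 (1), 18 and 108 in July 2009 (4), 359 and 275 in November 2009 (1), 0 and 1 in January 2010 (10), 1 and 1 in April 2010 (2) and 3 and 0 in July 2010 (1). Of the 4 July 2009 splits that part all same-numbered pairs, the real one gave 18 and the other 3 gave 0. That pairing was found in these same values, so those 4 splits lend the real one no support. For June 2007 minus January 2008 the 10 splits gave 83 and 545 (2), and for the UV difference in summer minus winter and for dates as replicates the 10 splits of 5 dates gave 0 with 654 and 302 as the highest others (10 each). The splits with 108 and 545 features, several times the real 18 and 83, and those with 654 and 302, where the real splits gave 0, point to a structure of the samples other than the groups compared, such as January 2008 replicates 1 and 3 with June 2007 replicate 1 against the rest, or August 2008, January 2010 and July 2010 against the other dates.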

How the results depend on the processing

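Tests chosen after the data were seen are those without the 4 arrays that stood apart, with the random-probe covariate, with the median of the 4 blocks and within slides. Of 6109 values of named genes under other settings, 5790 kept their direction and their side of the threshold, 148 lost the call and 150 gained it. Another 18, not called under the main setting, changed direction. The 3 called values that changed direction were of November 2009 with the slide as a block (CMM140C −0.18, CMV213C 0.41, CMW019C 0.92). Over 9900 values with 1 array left out, 9431 stayed, 333 lost the call and 97 gained it. There 39 values not called under the main setting changed direction, and 0 called ones did. With the whole-series table, median centring, the other variance model or the median of blocks, total counts stayed within 1.5 times of those in the report, except January 2010 (0, and 1 with the other variance model). This holds for totals and not for higher and lower calls apart. The cause was not tested unless given here. In what follows, counts are of features past the threshold. Signal over background limits dim features, of which 620 lay under 2 times the random-probe signal throughout a group.

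The count shared by 3 pairs (14) was 8 without the dimmest features and 9 after quantile normalization. Array weights, which give arrays close to their group more say, raised the mean UV count to 1414, the sum over dates to 7144, the F test over dates to 3742, summer minus winter UV to 693, July 2010 to 4490, Dragon Spring to 141, the site difference to 2058, February 2009 to 1504 and November 2009 to 1245. With the slide as a block they were 80 for the mean UV difference, 650 for the sum over dates, 17 for the F test, 2 for summer minus winter UV, 374 in February 2009, 0 by limma in November 2009 (where filters shared no slide group, 100 at an unadjusted p under 0.05), 131 at Dragon Spring and 25 shared by 3 pairs. A 2-fold threshold, stricter by construction, left 6, 358 over dates, 191 in February 2009, 152 in November 2009, 431 in July 2010, 653 in July 2009 and 39 at Dragon Spring. Fits on the compared arrays alone, with fewer samples, gave 201 in February 2009 and 203 over dates, and by limma 0 in November 2009 and 0 at Dragon Spring (743 and 475 at an unadjusted p under 0.05).

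Without the 4 arrays the counts were 551 for the mean UV difference, 2001 over dates, 621 for the F test, 18 for summer minus winter UV, 159 at Dragon Spring, 27 shared by 3 pairs, 1430 for the site difference and 1419 in February 2009. November 2009 had 303, with 95 higher and 208 lower against 239 and 120. With the random-probe covariate they were 122, 538 over dates, 400 for the F test, 406 in February 2009 and 68 in November 2009. Within slides they were 721, 634 over dates, 79 for the F test, 31 for summer minus winter UV and 296 in February 2009. Dates as replicates had 0, and 2292 with samples as replicates, 172 without August 2008 and 5 without January 2010. Camera's 21 list calls became 1 with an estimated correlation, 20 by fry (only 11 of them among camera's) and 17 to 27 under the other settings.

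Leaving out 1 array gave 184 to 755 for the mean UV difference, 348 to 1922 over dates, 1 to 527 for the F test, 0 to 3 for summer minus winter UV, 2 to 702 in February 2009, 0 to 1088 in November 2009, 14 to 183 at Dragon Spring, 0 to 17 shared by 3 pairs and 237 to 1216 for the site difference, with the arrays that moved a total by over 1.5 times named beside each result. Higher and lower calls moved apart from their totals in some fits, most of all the lower calls of the mean UV difference, which were 21 to 316. Over dates the lower calls were 183 without February 2009 UF-5 replicate 2, against 334. The ranges were 5932 to 6124 for the date F test, 1699 to 2008 for July 2010, 2324 to 2951 for July 2009 and 17 to 26 for list calls. Over dates the sum was 431, 670 and 348 without February 2009 OP-4 replicate 1, UF-5 replicate 1 and UF-5 replicate 3, 1606 without April 2010 UF-5 replicate 3, and 1922 and 691 without November 2009 UF-5 replicates 1 and 2.

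Replicate numbers were taken to pair the samples in July 2009 alone, and that pairing was read from the values. Same-numbered arrays of the 2 filters deviated together (r over 0.1 across features) in 11 of 21 pairs, from −0.553 to 0.535, and in 9 of the 21, with all 3 of July 2009, the own number correlated best. With the replicate number as a block the F test called 395 features and summer minus winter UV 7. July 2009 had 161 against 18, January 2010 1 against 0, April 2010 2 against 1 and July 2010 0 by limma against 3 (194 and 127 at an unadjusted p under 0.05). CMR353C was called in neither of the last 2 with that block (adjusted p = 0.112 in April and 0.705 in July), so the 2 of April are other features. The block moved none of the other counts fitted with it by over 1.5 times.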

Other observations

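Of the tests in this part, those on features shared by the 3 season pairs were chosen after the result was seen.

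Between the season pairs, features other than gene models also differed. Of 140 features that are sequence reads and not gene models, 54 were lower and 0 higher in July 2010 than in January 2010 (median −0.619), and 53 were lower and 16 higher in July 2009 than in February 2009. At Dragon Spring 10 were higher and 0 lower in June 2007. Repetitive elements went with them at Lemonade Creek, with 172 lower and 9 higher of 338 in 2010 (median −0.977) and 230 lower and 12 higher in 2009 (median −1.467), against 3 lower at Dragon Spring (median −0.16).

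A carotenoid enzyme and a cryptochrome, set side by side after their values were seen, were each higher under UV and in July at Lemonade Creek. Cryptochrome DASH CMJ130C rose under UV by 0.42, in July 2010 by 0.77 and in July 2009 by 0.85, and zeta-carotene desaturase CMT061C rose by 0.55, 1.01 and 0.78 in the same comparisons. The July pairs called 2091 features in 2010 and 2855 in 2009, and whether UV calls coincide with them beyond chance was not tested. Neither gene was called at Dragon Spring or with dates as replicates. The UV differences at different dates correlated across features with r from −0.551 (July 2009 with July 2010) to 0.598 (August 2008 with January 2010), and features are not independent replicates.

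Of the 8 protein-coding features lower in summer in all 3 pairs, 3 were in the list of 54 DNA replication and cell cycle genes, among 4935 protein-coding features. Fisher's exact test gave a two-sided p of 6.67e-05, which decides nothing, since it was chosen after those genes had been seen and takes co-expressed genes as independent draws. Other values do not bear out a fall in every summer. In the 2009 pair the whole list had 14 higher and 13 lower genes (camera adjusted p = 0.515), and the median difference of its 26 genes lower in July 2010 was 0.007 there. The shared count also fell to 0 without June 2007 replicate 3, and 3 of 20 labellings of the Dragon Spring arrays, the real one included, gave as many shared features or more, so the cause is left open.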
